A study of Mus musculus with 7 samples.

How the data were processed

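Single cells of 7 whole kidneys of adult C57BL/6 mice were profiled with the Chromium 3′ droplet method, per the labels. Per the submitters' processing notes, reads were processed with Cell Ranger 1.3 and STAR on mm10 (GRCm38.p4). The authors combined the libraries into a single deposited matrix of counts, in which each value is the UMI count of a gene in a cell, and added their cluster number of each cell. The notes given with the files do not state how cells were filtered or clustered. The values were checked to be whole and not negative, and cells held 201 to 2998 genes, 707 to 15000.0 UMIs and at most 50% mitochondrial UMIs, with every gene seen in at least 5 cells. The labels state 57979 cells and the matrix holds 43745.

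Libraries were read from the number that ends each barcode. No source links these numbers to the labelled samples, so the libraries were taken as 7 kidneys of a single group. For the same reason the planned exact permutation test of wild-type against reporter-line kidneys and the comparisons intended with wild-type kidneys alone were not run. Clusters were the authors' own and were described with 19 marker lists and by the genes with the largest fold over the mean of the other clusters, with a pseudocount of 10 CPM. Names such as principal-like are descriptions from these markers. Of the gene symbols in the matrix, 15721 were found in the gene-name table, and positions are from GENCODE vM21 on GRCm38.

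Raw counts were summed per library and cluster where at least 5 cells were present. They were tested with edgeR 4.0.16 (TMM normalization, filterByExpr by cluster, quasi-likelihood F test, a term for each cluster and each library) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The collecting duct fit held clusters 6, 7 and 8, with 6, 7 and 4 sums, and 6536 genes passed the filter. A fit of all 16 clusters gave the contrasts of a preset class with the mean of the other clusters, and of cluster 3 with the mean of the other tubule and collecting duct clusters. Gene lists were tested with limma 3.58.1 (voom and camera with a preset correlation of 0.01, adjusted over the lists), with an estimated correlation and fry as alternatives. The position of cluster 8 is the median over called genes of its log2 distance from principal-like cells divided by that of intercalated-like cells, with its range over leaving out each library in turn. Levels are CPM of the library sums, given as mean ± SD over libraries.

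The 18 gene lists, the marker lists, the tests, most of the alternative settings and the rule for named genes were fixed before the data were examined. By that rule, the 12 genes with the largest fold in each direction are named between intercalated-like and principal-like cells, among those with an adjusted p under 0.05, an average log2 CPM of at least 6, at least 10 counts in each arm and the same sign in every library with both clusters. For cluster 8 the rule takes 6 genes per direction against each type and up to 8 genes above both. For lists it takes up to 6 members with the highest level and up to 3 that are highest in another cluster. All Notch members and V-ATPase subunits may be named, and for clusters up to 4 markers and 5 leading genes. Exceptions chosen after their values were seen are Hadha and Hadhb, the haemoglobin genes by library, Xist, Jchain, and the sex-biased and monocyte genes of the closing section.

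Depth per library and per cell is given at the start of the report. The test was tested on simulated data, with changes added to 200 of 6536 genes at the depth and sums used here. The spread was set by hand, not estimated from the data, and fewer genes changed than were called in the data. The rates below hold for those settings only. Between intercalated-like and principal-like cells it recovered 68% of 2-fold and 100% of 4-fold changes, with 6 unchanged genes called, and between cluster 8 and principal-like cells 16% and 69%, with 1 unchanged gene called. Shares of a single library carry 95% Wilson intervals and levels of a single library exact Poisson intervals, which hold counting error only, and a count of 0 is given an upper limit of 3 counts. Other splits exchanged cluster labels within libraries, for 32 splits between intercalated-like and principal-like cells and 8 for each cluster 8 comparison.

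Alternatives tried were DESeq2 1.42.0 with its Wald test, its size factors in edgeR, no low-count filter, at least 20 cells per sum, each library left out, each cell thinned to 1000.0 UMIs (2494 shallower cells left out), no library block, and only the compared clusters in the fit. Scrublet (in scanpy 1.11.5, expected rate 0.06, 30 components) marked 51 cells, 0.117% of all, with its automatic threshold, so the planned removal of its calls was not run. Removal of the 6% of cells with the highest scores in each library, and the linear scale for the position of cluster 8, were added after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest. Reads were not analysed here, so intron and exon counts, empty droplets and genotype could not be examined. Results of some genes are not reported here, though they remain in the counts of genes and lists.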

Results

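Whole kidneys of 7 healthy adult C57BL/6 mice, aged 4 to 8 weeks per the labels, were dissociated and profiled by droplet-based single-cell RNA sequencing of transcript 3′ ends, in which every captured molecule carries a unique molecular identifier (UMI). Per the labels, 4 mice were wild type and 3 carried a Cre-dependent fluorescent membrane reporter, each with a different Cre driver, and the sex of the animals is not stated. The deposited matrix held 16272 genes and 43745 cells, against 57979 cells stated in the labels, and gave the authors' cluster number (1 to 16) for every cell. Cells fell into 7 libraries by the number that ends each cell barcode. No source used here links these numbers to the labelled mice, so the libraries are called 1 to 7 by barcode number and were treated as 7 kidneys of a single group. The libraries held between 1383 cells (library 3) and 14136 cells (library 5). Total UMIs were 5883163, 14168771, 4217169, 7433555, 49997616, 26001207 and 14436028 in libraries 1 to 7. Median UMIs per cell ranged from 1630.0 in library 1 to 3115 in library 5, and median mitochondrial shares from 17.1% to 23.3%.

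The first question was which cell types the kidneys yielded and in what proportion. Proximal tubule-like cells (cluster 3) were the most abundant in each of the 7 libraries, at 56.8% ± 13.7 of a library's cells (SD, n = 7, range 39.9% to 74.6%), followed in the mean by distal convoluted tubule-like cells (cluster 5) at 17.3% ± 5.48. Loop of Henle-like cells (cluster 4) made up 5.39% ± 3.32, intercalated-like cells (cluster 7) 4.75% ± 2.48, principal-like cells (cluster 6) 1.92% ± 1.28, endothelial-like cells (cluster 1) 3.41% ± 2.12 and podocyte-like cells (cluster 2) 0.126% ± 0.083. Dissociation sets how many cells of each type are recovered, so these are shares of captured cells, not of the tissue.

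The tubule clusters carried the transporters of their segments. Cluster 3 was led among the fixed markers by Miox, which encodes the enzyme that oxidises myo-inositol, and the dicarboxylate transporter Slc13a3, and 13 of 15 proximal markers were highest there. Its largest folds over the mean of the other clusters belonged to the haemoglobin genes Hbb-bs and Hba-a1, which come from red blood cells and lay mostly in 3 libraries. Across all cells, Hbb-bs reached 1339 CPM (UMIs of a gene scaled to the same total for each sum) in library 3 (exact Poisson 95% interval 1304 to 1374), 396 in library 4 (382 to 410.2) and 322 in library 2 (312 to 331), intervals of counting error only. Cluster 4 was led by the sodium-potassium-chloride cotransporter Slc12a1 at 4335 ± 578 CPM (mean ± SD, n = 7), by Umod (uromodulin) and by the tight junction genes Cldn19 and Cldn16. Cluster 5 was led by the thiazide-sensitive cotransporter Slc12a3 at 3379 ± 412 CPM (mean ± SD, n = 7), by Pvalb and by the magnesium channel Trpm6, and had the highest median mitochondrial share of the 16 clusters, 31.7% of a cell's UMIs. In cluster 6 the leading genes were Fxyd4, the water channel Aqp2 and Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids. In cluster 7 they were the proton pump subunits Atp6v1g3 and Atp6v0d2, with Aqp6, the transcription factor gene Hmx2 and the anion exchanger Slc4a1.

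Outside the tubule, the leading genes of cluster 2 included the slit diaphragm gene Nphs1 (1707 ± 192 CPM, mean ± SD, n = 4), and cluster 1 was led by Emcn, Plpp1 and Kdr. Cluster 1 also held the highest level of 6 of 8 pericyte, mesangial or smooth muscle markers, 3 of 6 fibroblast markers and all 4 measured urothelial markers, so its 1001 cells were not endothelial alone. Immune clusters were macrophage-like (cluster 11, led by the complement genes C1qa, C1qb and C1qc), neutrophil-like (cluster 12, S100a8 and S100a9), B lymphocyte-like (cluster 13, Jchain, Mzb1 and Cd79a), T lymphocyte-like (cluster 14, Cxcr6, Il7r and Cd3g) and natural killer-like (cluster 15, Ccl5, Gzma and Ncr1). Their mean shares were 0.724% ± 0.706, 0.175% ± 0.062, 0.74% ± 0.504, 4.99% ± 5.21 and 1.29% ± 1.47 (SD, n = 7). The macrophage-like share was 0.477% without library 1. In percentage points T lymphocyte-like cells had the widest range of these, from 0.73% of library 7 (95% Wilson interval 0.535% to 0.996%) to 13.98% of library 4 (12.7% to 15.3%), intervals of counting error only. Libraries 3 and 4 stood apart together for some classes, which a mean ± SD does not show. T lymphocyte-like cells made up 10.85% of library 3 as well, against 3.296% in library 1, the next highest. Natural killer-like cells were at 3.76% and 3.07% in libraries 3 and 4, against at most 0.578% elsewhere. Intercalated-like cells were at 8.098% and 8.543% there, against at most 3.786% elsewhere. What sets these libraries apart was not tested. Cluster 9 joined proliferation genes (Lockd, Mki67, Cenpf) with proximal tubule genes, and 552 of its 601 cells came from library 5, so its mean share of 0.727% became 0.197% without that library. Cluster 16, with 42 cells, joined Hist1h2ap, Ube2c and Birc5 with lymphocyte genes. Cluster 10 (549 cells, led by Plac8, Lyz2 and Ms4a6c) was left unnamed because no single marker list described it.

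**Figure D1:**
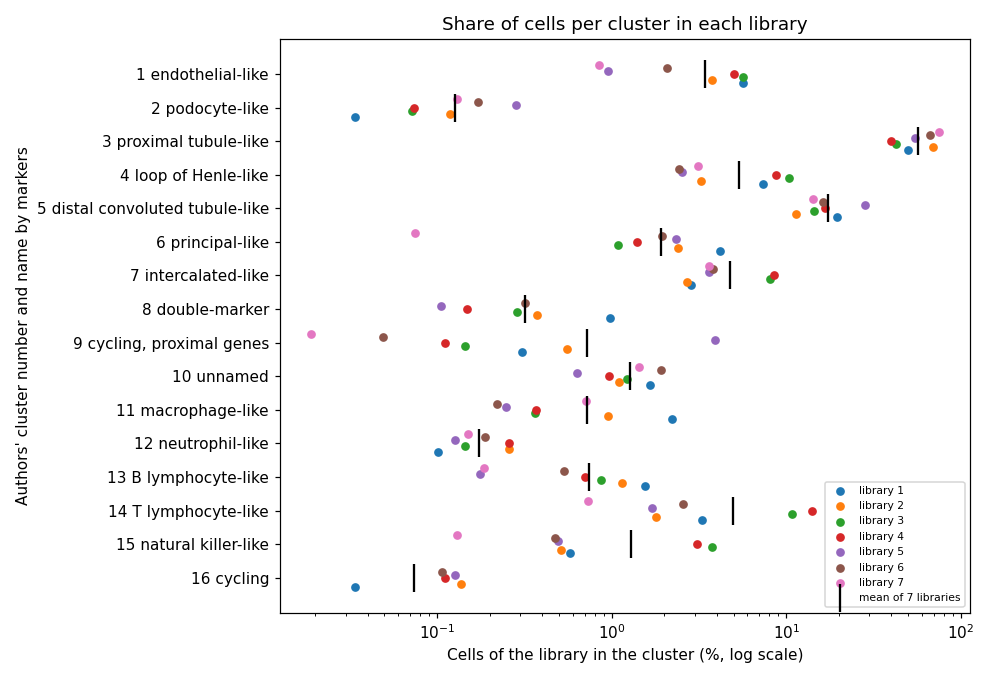
Share of each library's cells in each of the authors' 16 clusters (log scale, percent), with 1 point per library and a bar at the mean of 7 libraries; a cluster with no cells in a library has no point. Cluster 9 stands at 3.91% in library 5 (95% Wilson interval 3.60% to 4.24%) and at 0.553% (0.383% to 0.799%) or less in the other 6 libraries, counting error only.

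The collecting duct holds principal cells, which reabsorb water and sodium, and intercalated cells, which handle acid and base, and the next comparison asked how far their transcript profiles differ. Intercalated-like cells carried far more RNA for the proton pump, the anion exchangers and their regulator Foxi1, and principal-like cells far more for the water channel Aqp2, the vasopressin receptor and the sodium channel subunits Scnn1b and Scnn1g. Split by type A and type B intercalated genes, cluster 7 held 678 type A cells, 939 type B cells and 112 of neither. Its levels pool these, so genes such as Slc4a1 and Slc26a4 need not be high in the same cells. Slc26a4 (ENSMUSG00000020651), which encodes the chloride and bicarbonate exchanger pendrin, was higher in intercalated-like cells by 7.43 ± 0.268 on the log2 scale (fold ± SE, 7 against 6 library sums). Aqp2 (ENSMUSG00000023013) had a log2 fold change of -8.23 ± 0.28, with mean levels of 6107 ± 2370 CPM in principal-like (SD, n = 6) and 12.6 ± 12.9 CPM in intercalated-like cells (SD, n = 7). Of 6536 genes tested with edgeR's quasi-likelihood test, 1143 were higher and 1078 lower in intercalated-like cells at an adjusted p under 0.05, and 426 and 558 of these changed at least 2-fold.

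Among the 12 genes with the largest rise by the fixed rule, 3 encode V-ATPase subunits, Atp6v1g3 (log2 fold 7.38 ± 0.205), Atp6v0d2 (7.03 ± 0.241) and Atp6v1c2 (6.80 ± 0.246). The others were Slc26a4, Aqp6 (7.14), Slc4a1 (6.83), Ociad2 (6.58), Foxi1 (6.34), Guca2a (5.80), Emb (5.74), Rcan2 (5.55) and Pam (5.37). The edgeR adjusted p was 1.98e-23 for Atp6v1g3 and 8.7e-21 for Slc26a4. In the other direction the largest changes were those of Aqp2, the sodium pump regulator Fxyd4 (-8.12 ± 0.273), the peptide hormone gene Apela (-7.81 ± 0.207), Hsd11b2 (-6.61), the vasopressin receptor gene Avpr2 (-6.52) and Kcne1 (-6.39). Npnt (-5.62), Cav1 (-5.56), Tmem45b (-5.42), Ptgs1 (-4.91) and the sodium channel subunit Scnn1g (-4.77) followed, and Aqp2 had an edgeR adjusted p of 2.93e-21. The rule required the same direction in all 6 libraries that held both cell types. That was thus a condition for the 24 genes it takes, not a result.

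On the GRCm38 assembly, Slc26a4 lies on chromosome 12 from 31519827 to 31559969, Atp6v1g3 (ENSMUSG00000026394) on chromosome 1 from 138273738 to 138289462, and Foxi1 (ENSMUSG00000047861) on chromosome 11 from 34204338 to 34208089. Aqp2 lies on chromosome 15 from 99579055 to 99584547, on the same strand as Aqp6 (ENSMUSG00000043144), which starts at 99601400, and Hsd11b2 (ENSMUSG00000031891) on chromosome 8 from 105518755 to 105523988. All are protein-coding genes in the annotation, and the counts are per gene, without a split by exon or transcript.

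The gene lists fixed beforehand separated along the same lines, but they share genes with the markers that named the clusters. Of the water and sodium genes, Aqp2, Avpr2, Scnn1b, Scnn1g and Hsd11b2 are also principal markers. Atp6v1b1, Atp6v0a4, Slc4a1 and Foxi1 of the acidosis genes and Atp6v1g3 and Atp6v0d2 of the V-ATPase genes are also intercalated markers. The direction of these members followed largely from the naming, so the list p-values are not independent of it. Of 21 V-ATPase subunit and accessory genes tested, 16 rose and 2 fell in intercalated-like cells (camera adjusted p = 3.54e-13, adjusted p = 0.0255 with an estimated correlation). Among the other subunits that rose were Atp6v1d (2.74), Atp6v0a4 (2.28), Atp6v0b (2.22), Atp6v1e1 (2.11) and Atp6v1a (1.76), while Atp6v0d1 fell by 0.80 and Atp6v0e2 by 1.37 on the log2 scale. All 6 distal renal tubular acidosis genes rose (camera adjusted p = 1.08e-09, adjusted p = 0.00218 with an estimated correlation), among them Car2 (1.79) and Atp6v1b1 (1.97). All 7 water and sodium disorder genes of the collecting duct fell (camera adjusted p = 6.89e-11, adjusted p = 0.00218 with an estimated correlation), including Scnn1b (-3.00) and Scnn1a (-0.82). Adjusted over the list alone, the counts of these lists were the same, at 16 and 2, 6 and 7.

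Genes of the respiratory chain were higher in intercalated-like cells, with 39 of 40 nuclear oxidative phosphorylation genes past the test and 40 of 40 adjusted over the list alone. Their summed level was 57795 ± 4683 CPM in intercalated-like (SD, n = 7) and 37621 ± 3699 CPM in principal-like cells (SD, n = 6), with Atp5g1 (1.18), Ndufa4 (0.94), Cox6c (0.81) and Cox4i1 (0.74) as examples. The camera adjusted p was 2.63e-22, but adjusted p = 0.136 with an estimated correlation, since members of this list vary together. Of 13 mitochondrially encoded genes 9 rose, and 10 did so adjusted over the list alone (camera adjusted p = 0.00179, adjusted p = 0.455 with an estimated correlation). The median mitochondrial share was 23.5% of UMIs in intercalated-like and 21.6% in principal-like cells.

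Notch signalling genes divided between both cell types. The ligand Jag1 (ENSMUSG00000027276, chromosome 2, 137081456 to 137116644) was higher in intercalated-like cells by 3.15 ± 0.218 (log2 fold ± SE, edgeR adjusted p = 1.2e-13, 6 of 6 libraries) and the ligand Dll1 by 2.94 ± 0.502. Dll4 had 123 UMIs in intercalated-like and 1 in principal-like cells and also passed the test, while Mib1, which encodes a ligase that activates ligands, fell by 0.84. The receptor gene Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361) had a log2 fold change of -4.38, and the target genes Nrarp (-4.51) and Hes1 (-1.62; ENSMUSG00000022528, chromosome 16, 30064384 to 30067796) fell as well. Rbpj, the transcription factor of the pathway, did not pass the test (0.30 ± 0.245, edgeR adjusted p = 0.387). As lists, 3 of 4 receptor and target genes tested fell (camera adjusted p = 0.00355, adjusted p = 0.0536 with an estimated correlation), and 3 of 4 ligand genes rose and 1 fell (camera adjusted p = 0.0543). The ligand list gave 0.0392 without library 1. Adjusted over the list alone, both Notch lists had the same counts.

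Of 12 collecting duct transcription factor genes, 4 rose (Hmx2 by 7.40 and Foxi1 by 6.34, with Dmrt2 and Esrrg) and 6 fell (Tfap2b -2.74, Gata2 -2.32 and Hoxd8 -1.02, with Ehf, Gata3 and Hoxb7). Adjusted over the list alone, 5 rose and 6 fell, and the list had no direction as a whole (camera adjusted p = 0.376, median log2 fold -0.39 and mean 0.70, which differ in sign). Tfcp2l1, a regulator of collecting duct cell identity, was at 0.29 ± 0.12 (edgeR adjusted p = 0.0664). Immediate early and heat shock genes, which rise during tissue dissociation, included 7 of 15 that fell and 1 that rose, also adjusted over the list alone, and Junb fell by 1.87 and Fos by 1.57, while Hspa8 rose by 0.41. The camera adjusted p of that list was 0.14, and 0.043 without library 6.

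Nephrotic syndrome genes (1 of 8 rose and 5 fell) and cystic kidney genes (3 of 6 fell, 5 adjusted over the list alone) each had a camera adjusted p of 0.0496, with adjusted p = 0.136 and adjusted p = 0.181 with an estimated correlation. Leaving out libraries 1, 2, 5, 6 or 7 moved the first to 0.0504, 0.0537, 0.0681, 0.0526 and 0.0514, and leaving out libraries 1, 2, 3, 4 or 7 moved the second to 0.0563, 0.0537, 0.0521, 0.0572 and 0.0514. Removing the cells with the highest doublet scores, added after seeing the data, moved them to 0.0522 and 0.0893. Fatty acid oxidation (5 of 20 rose, 2 fell, camera adjusted p = 0.329), glycolysis (2 of 14 rose, 2 fell, 0.888, with a median of -0.07 against an upward test direction) and gluconeogenesis (2 of 5 fell, 3 adjusted over the list alone, 0.376) had no direction past the test. Neither did proximal transport disorder genes (1 of 11 rose, 4 fell, camera adjusted p = 0.311), Bartter genes (2 of 6 rose, 3 fell, 0.329), Gitelman genes (1 of 8 rose, 2 fell, 0.401) or chronic kidney disease association genes (4 of 19 rose, 8 fell, 9 adjusted over the list alone, 0.311). The authors set the clusters on these same counts, for the cells of every library. Genes that part both clusters thus tend to differ in every library by the assignment itself. Their p-values are not independent evidence that the types exist or that they recur across kidneys.

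Cluster 8, with 110 cells, carried markers of principal and intercalated cells together, and the comparisons with each type asked where its profile lies. Principal markers stood 3.71 and intercalated markers 4.13 (mean log2) above their all-cluster means there. These are levels of counts summed over cells, and how many single cells held both marker sets was not counted. Cluster 8 was picked out for carrying both sets. Genes that the V-ATPase, distal renal tubular acidosis and water and sodium lists share with those markers are thus no independent test in the comparisons below. Mean levels in cluster 8 were 1634 ± 466 CPM for Aqp2 and 2010 ± 449 CPM for Hsd11b2 (SD, n = 4), together with 5702 ± 749 CPM for Atp6v1g3 and 1129 ± 324 CPM for Slc26a4. Its cells held a median of 5330.0 UMIs, against 2895 in principal-like and 3917 in intercalated-like cells. The cluster made up 0.318% ± 0.323 of cells (SD, n = 7), or 0.207% without library 1, and 4 libraries had the 5 cells needed for a sum.

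Against principal-like cells, 376 genes were higher and 377 lower in cluster 8 (edgeR, adjusted p under 0.05, 4 against 6 library sums). The largest rises by the fixed rule, which required the same direction in 4 of 4 libraries, were Slc26a4 (7.50 ± 0.29), Aqp6 (6.73 ± 0.32), Atp6v1g3 (6.63 ± 0.214), Atp6v1c2 (6.49), Slc4a1 (6.42) and Atp6v0d2 (6.39). The largest falls by the same rule were the kallikrein gene Klk1 (-3.14 ± 0.416), the gluconeogenic gene Pck1 (-2.42), Igfbp7 (-2.21), the noncoding Snhg18 (-2.04), Akr1c21 (-2.03) and Fxyd4 (-1.99). Pck1 and Akr1c21 have their highest level in proximal tubule-like cells (984 and 1266 CPM), and the share of free RNA from those cells was not measured. Of 21 V-ATPase genes 13 rose (camera adjusted p = 3.49e-18, adjusted p = 0.00761 with an estimated correlation), all 6 distal renal tubular acidosis genes rose (1.58e-15, and adjusted p = 0.000523 with an estimated correlation), and 5 of 7 water and sodium genes fell, 6 adjusted over the list alone (7.37e-09, and adjusted p = 0.00761 with an estimated correlation). Proximal transport disorder genes, which mark another segment, fell in 6 of 11 cases, 9 adjusted over the list alone, and 1 rose (camera adjusted p = 0.00232, adjusted p = 0.139 with an estimated correlation). Oxidative phosphorylation genes rose in 9 of 40 cases, 13 adjusted over the list alone (camera adjusted p = 1.58e-06, adjusted p = 0.461 with an estimated correlation).

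Against intercalated-like cells, 259 genes were higher and 321 lower (edgeR, 4 against 7 library sums). By the same split, cluster 8 held 36 type A cells, 71 type B cells and 3 of neither, against 678, 939 and 112 in cluster 7. The comparison was not adjusted for this mix. Aqp2 (6.38 ± 0.293), Apela (6.35 ± 0.256), Fxyd4 (6.13 ± 0.307), Hsd11b2 (5.44), Kcne1 (5.04) and Avpr2 (4.56) led the rises. Klk1 (-2.77), Pck1 (-2.31), Akr1c21 (-1.71), Miox (-1.61), 9130008F23Rik (-1.46) and Sult1d1 (-1.43) led the falls. For all 12 the rule required the same direction in 4 of 4 libraries. The limit on free RNA applies here too, to Pck1, Akr1c21, Miox and Sult1d1, the last 2 at 2209 and 612 CPM in proximal tubule-like cells. Of 7 water and sodium genes 6 rose (camera adjusted p = 2.63e-17, adjusted p = 0.000942 with an estimated correlation). Oxidative phosphorylation genes fell in 23 of 40 cases, 27 adjusted over the list alone (camera adjusted p = 6.34e-22, and adjusted p = 0.127 with an estimated correlation), mitochondrially encoded genes in 5 of 13, 6 adjusted over the list alone (camera adjusted p = 1.28e-06, and adjusted p = 0.231 with an estimated correlation), and V-ATPase genes in 8 of 21, 9 adjusted over the list alone (camera adjusted p = 7.38e-06, and adjusted p = 0.127 with an estimated correlation). Proximal transport disorder genes fell in 3 of 11 cases and rose in 1, with 5 falling adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.172 with an estimated correlation). The count of lower genes rested on single libraries: 321 became 143, 186, 192 and 157 without libraries 1, 2, 5 and 6, and the 259 higher genes became 155 and 172 without libraries 1 and 2. Against principal-like cells the 377 lower genes became 239 without library 2.

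Among Notch genes, the ligand gene Jag1 in cluster 8 was far above its principal-like level, and Hes1 and Notch2 differed from both types. Jag1 averaged 150.4 ± 27.8 CPM in cluster 8 (SD, n = 4), 124 ± 30.5 in intercalated-like and 18.5 ± 10.3 in principal-like cells, and the edgeR adjusted p was 2.28e-09 against principal-like and 0.785 against intercalated-like cells. Hes1 averaged 407 ± 116 CPM, between 666 ± 149 in principal-like and 187 ± 73.6 in intercalated-like cells, and differed from both (log2 fold -0.88, edgeR adjusted p = 5.83e-05, and 0.74, edgeR adjusted p = 0.00172). Notch2 did likewise (-1.57 ± 0.459, edgeR adjusted p = 0.0196, and 2.81 ± 0.687, edgeR adjusted p = 0.00782) on 9 UMIs in cluster 8. Levels between both types would also arise from a principal and an intercalated cell captured together. Receptor and target genes as a list rose against intercalated-like cells in 3 of 4 cases (camera adjusted p = 0.000478, adjusted p = 0.0421 with an estimated correlation). Against principal-like cells 2 of 4 fell, and the list did not pass the test (camera adjusted p = 0.0608).

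Over the 2221 genes that differed between both types, cluster 8 lay near the middle. It was picked out for carrying both marker sets, so a position between both types was likely from the start. Such a position cannot tell an intermediate cell type from cells of both types captured together. On a scale with 0 at the principal-like and 1 at the intercalated-like level, its median position was 0.539 (0.518 to 0.563 with each library left out, though only 4 libraries hold a sum of cluster 8). It was 0.649 (0.639 to 0.670) for the 1143 genes higher in intercalated-like cells and 0.476 (0.439 to 0.498) for the 1078 genes higher in principal-like cells. On the linear scale, added after seeing the data, these were 0.547 and 0.632, so the order of both sets depends on the scale. Only 6 genes were higher in cluster 8 than in both types, and 75 were lower than in both. By the fixed rule 3 of the 6 may be named, the coatomer gene Arcn1 (1.08 ± 0.231 over principal-like and 0.85 ± 0.219 over intercalated-like cells), Hnrnpab (0.68 and 0.64) and Ddx6 (0.57 and 0.64). Against principal-like cells and both parts of a split intercalated-like cluster, Arcn1 stayed above in 20 of 20 reference draws and Hnrnpab in 1, and Ddx6 in none. The draws shared the same cluster 8 sums and most reference cells, so they are not replicates.

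**Figure D2:**
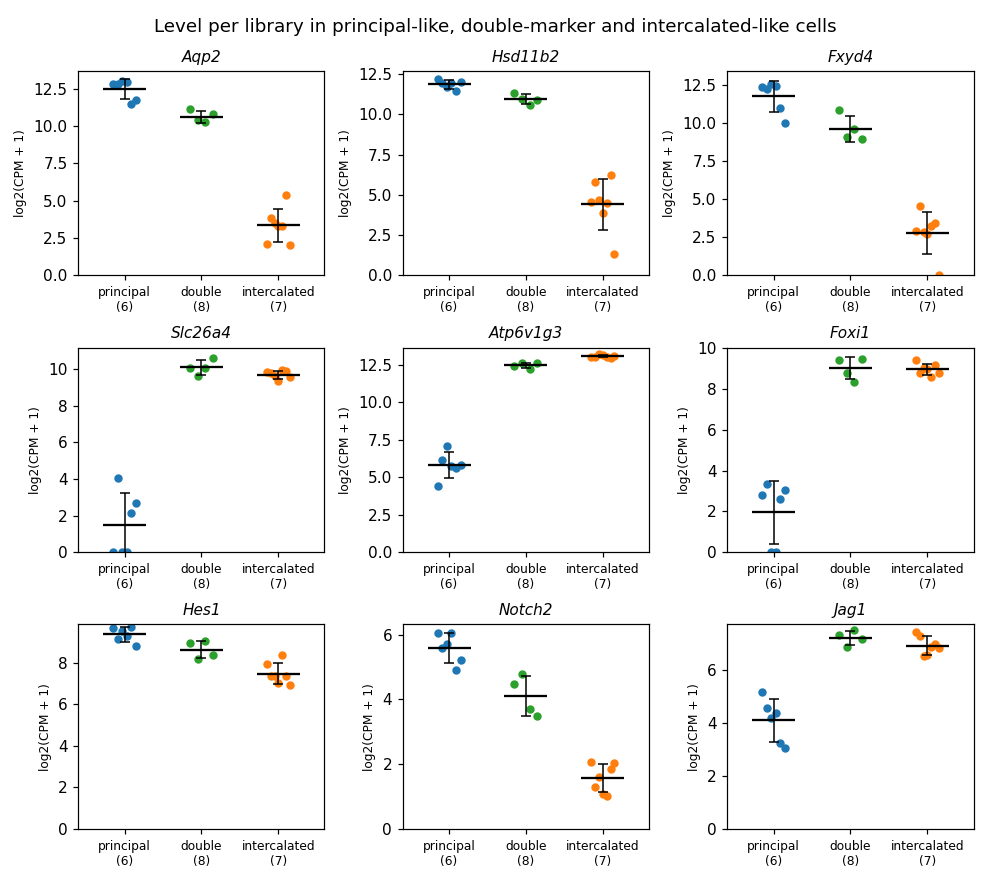
Level of 9 genes, as log2(CPM + 1), in principal-like (cluster 6, 6 libraries), double-marker (cluster 8, 4 libraries) and intercalated-like cells (cluster 7, 7 libraries), with 1 point per library, a bar at the mean and whiskers of 1 SD. Aqp2 and Atp6v1g3 are both high in cluster 8, Jag1 is at its intercalated-like level, and Hes1 and Notch2 lie between both types.

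Segments of the tubule differ in fuel use, and the lists of metabolic genes asked whether proximal tubule-like cells stood apart from the other tubule and collecting duct clusters. All 6 gluconeogenesis genes were higher in proximal tubule-like cells, with a summed level of 4944 ± 662 CPM in cluster 3 (SD, n = 7) against 349 ± 202 in intercalated-like cells. The log2 folds over the mean of the other epithelial clusters were 4.47 ± 0.186 for Pck1, 4.36 ± 0.193 for G6pc, 3.87 for Fbp1, 3.07 for Slc37a4 and 2.70 for Pcx (camera adjusted p = 3.19e-07, adjusted p = 0.0148 with an estimated correlation). Glycolysis ran the other way: 8 of 15 genes fell, such as Pkm (-5.08 ± 0.2), Ldhb (-1.22 ± 0.183) and Aldoa (-1.11 ± 0.128), and 2 rose, Ldha (1.04) and Gapdh (0.67), with a camera adjusted p of 0.00588 and adjusted p = 0.118 with an estimated correlation.

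Of 21 fatty acid oxidation genes 13 rose and 2 fell in proximal tubule-like cells (camera adjusted p = 0.00588, adjusted p = 0.204 with an estimated correlation). Among the members with the highest levels, Hadh rose by 1.52 ± 0.126, Acadm by 1.02 ± 0.13 and Etfb by 0.79 ± 0.136, while Echs1 was at -0.17 (edgeR adjusted p = 0.294). The members that fell were Hadha (-1.05) and Hadhb (-1.09), both subunits of the mitochondrial trifunctional protein, named here after their values were seen. Oxidative phosphorylation genes summed to 36700 ± 3695 CPM in cluster 3, below 55762 ± 7406 in distal convoluted tubule-like and 57795 ± 4683 in intercalated-like cells (SD, n = 7 each). The level in cluster 3 was close to 37621 ± 3699 CPM in principal-like cells (SD, n = 6). Of these 40 genes 16 fell and 3 rose, but the list did not pass the test (camera adjusted p = 0.125). Adjusted over the list alone, the counts of the gluconeogenesis, glycolysis and fatty acid oxidation lists were the same, and 14 oxidative phosphorylation genes fell.

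Genes of inherited kidney disorders were compared with the class in which each disorder is placed by its physiology, to see where they are used. Nephrotic syndrome genes were concentrated in podocyte-like cells, where 14 of 16 tested passed as higher than the mean of the other clusters, 15 adjusted over the list alone, and 16 of 17 measured had their highest level. Nphs1 (log2 fold 12.40 ± 0.291) and Wt1 (11.20 ± 0.446) are examples, and Anln, a gene of cell division, was highest in proliferating cluster 9. Proximal transport disorder genes were higher in proximal tubule-like cells in 18 of 19 cases, with Slc34a1, the phosphate transporter (3.79 ± 0.151), and the endocytic receptor Lrp2 (3.79 ± 0.157) as examples. Only 12 of 20 had their highest level there, and of the 8 others those with the highest levels were Gatm and Slc5a2, highest in proliferating cluster 9, and Clcn5, highest in intercalated-like cells (254 ± 41.5 CPM, against 251 ± 86.5 in cluster 8).

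Bartter and loop magnesium disorder genes were higher in loop of Henle-like cells in 9 of 9 cases, with Slc12a1 at 7.61 ± 0.19 and Umod at 6.13 ± 0.185, but Kcnj1 was highest in principal-like cells and Bsnd in the intercalated-like mean (228 ± 65.1 CPM, against 205 ± 98.8 in cluster 8). Gitelman and distal tubule disorder genes were higher in distal convoluted tubule-like cells in 11 of 11 cases, with Slc12a3 at 6.12 ± 0.179, and 7 of 11 had their highest level there. Of the others Egf was highest in loop of Henle-like cells, Kcnj10 in principal-like cells and Cul3 in the mean of cluster 8 (107 ± 56.6 CPM, against 72.2 ± 34.3 in principal-like cells). Water and sodium disorder genes were higher in principal-like cells in 7 of 7 cases (Aqp2 8.49 ± 0.179, Hsd11b2 8.05 ± 0.196), and Scnn1a had similar means in cluster 8 (473 ± 67.6 CPM) and principal-like cells (462 ± 68.4). Distal renal tubular acidosis genes were higher in intercalated-like cells in 6 of 6 cases (Slc4a1 8.67 ± 0.169, Foxi1 7.71 ± 0.173), and the means of cluster 8 and intercalated-like cells lay within 1 SD of each other for Atp6v0a4 (585 ± 111 and 572 ± 101 CPM) and Foxi1 (539.8 ± 186 and 503 ± 101 CPM). Between these clusters the list was lower in cluster 8, with 2 of 6 genes past the test, also adjusted over the list alone (camera adjusted p = 0.00337, adjusted p = 0.087 with an estimated correlation). Except for nephrotic syndrome, the counts of these lists adjusted over the list alone were the same. Several members of the inherited disorder lists, such as Nphs1, Lrp2, Slc12a1, Slc12a3, Aqp2 and Slc4a1, are also markers that named the clusters. Their direction is not independent of the naming.

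Chronic kidney disease association genes are drawn from loci mapped in human populations. Against the preset proximal class 17 of 24 tested were higher and 2 lower, also adjusted over the list alone, and 9 of 28 measured had their highest level in proximal tubule-like cells. The contrast was with the mean of the other clusters, and the share of all genes that pass it was not counted. The summed level was 6585 ± 559 CPM in cluster 3, against 10134 ± 1560 in loop of Henle-like and 7533 ± 1865 in macrophage-like cells (SD, n = 7 each). Such sums weigh abundant members most. Nat8 (3.94 ± 0.148), Slc47a1 (3.93 ± 0.17), Gatm (3.22 ± 0.151) and the endocytic adaptor gene Dab2 (2.40 ± 0.156) were among the higher genes. Umod (-1.71 ± 0.293) and Cst3 (-1.83 ± 0.238) were lower, with their highest levels in loop of Henle-like and macrophage-like cells, and Igfbp5 (1.60 ± 0.209) was highest in the endothelial-like cluster. Several members mark the clusters they were tested in, and the clusters were set on the same counts.

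**Figure D3:**
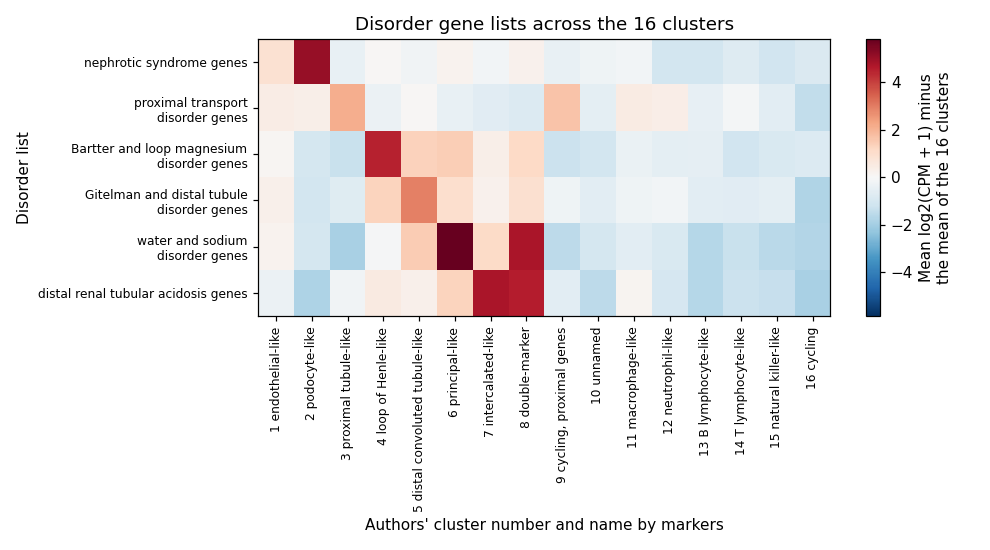
Level of the disorder lists (vertical axis) in the 16 clusters (horizontal axis), as the mean over measured members of log2(mean CPM + 1) minus each member's mean of the 16 clusters. Nephrotic syndrome genes are highest in podocyte-like cells and distal renal tubular acidosis genes in intercalated-like cells and cluster 8.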

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

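Among 48 groups of libraries, 7 values lay far from the other libraries by Dixon's test, which chance alone gives in about 1 in 20 groups, and 6 of them are given here. That rate does not hold for Xist, Hbb-bs, Hba-a1 and Jchain, which entered these groups after their values were seen. The tests of random pairing, UMIs per cell, free RNA, placement by 2 different genes and a library of mixed sexes were chosen only after the result was seen. So was the comparison of cycling cells of other types with the highest other library, after thinning and with 2 different genes. The examination of Xist, Hbb-bs, Hba-a1 and Jchain was likewise chosen after the result was seen.

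Cluster 8, with principal and intercalated markers in the same cluster, held 0.985% of library 1 (95% Wilson interval 0.687% to 1.41%, counting error only), against a median of 0.289%. How many of its single cells held both marker sets was not counted. Random pairing of a principal with an intercalated cell is excluded as the sole source, since it would need a doublet rate of 0.63 to 4.13 per cell in the 4 libraries used. Free RNA of the whole suspension is excluded too, since proximal tubule markers stood at 0.523 ± 0.163 of their level in the intercalated cluster (mean ± SD of 4 libraries), while free RNA of principal cells alone was not tested. Pairs of cells that stayed attached remain open. Cluster 8 had 0.757 ± 0.172 times the UMIs of simulated pairs (SD of 4 libraries). Of its genes, 4 (median of 20 draws on the same cluster 8 sums, range 1 to 6) lay above all references, against 0 in simulated pairs. The prediction written beforehand would have excluded such pairs on that count, but 60.5 genes lay below all references, against at most 3 in simulated pairs, and simulated pairs by construction carry the free RNA of 2 droplets and are an imperfect reference; a transitional cell type may be present but was not separated from attached pairs.

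Cluster 9, cycling cells with proximal tubule genes, held 3.905% of library 5 (95% Wilson interval 3.60% to 4.24%, counting error only; median of libraries 0.145%). Depth is excluded as the cause, since after thinning the share of cycling cells in library 5 was still 3.98 times that of the highest other library. Placement of such cells in cluster 3 elsewhere gave a ratio of 1.4 at full depth, which by the prediction written beforehand would have fitted, but 94.4% of the list's UMIs in those cells of libraries 3 and 4 were Stmn1, and with 2 different genes after thinning the ratio was 6.6, which excludes it. Cycling lymphocytes are excluded, with lymphocyte markers at 0.000234 of their level in cluster 16. A rise in every cell type met the prediction written beforehand, with 4.93 times the median of other libraries in distal convoluted tubule-like cells of library 5, but was left open after library 4 was seen to be nearly as high (1.075%, Wilson interval 0.799% to 1.44%, against 0.889%, 0.346% to 2.26%, in library 4, and 8 of 4000 against 1 of 4071 cells after thinning); T lymphocyte-like cells had 4.149% (2.27% to 7.47%) against 4.396% (1.72% to 10.8%) in library 2 (thinned 2.075%, 0.889% to 4.76%, against 1.099%, 0.194% to 5.96%), endothelial-like cells 5.185% (2.53% to 10.3%) against 3.012% (1.29% to 6.86%) in library 1 (thinned 2.222%, 0.759% to 6.33%, against 1.099%, 0.302% to 3.92%, in library 2), and free RNA of cycling cells was not tested; all 5 male-biased genes measured were lowest in library 5 among the libraries with Y-linked counts, so a younger or low-androgen male is one possible source.

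Xist stood at 2736 CPM in library 7 (exact Poisson 95% interval 2709 to 2763, counting error only; median of libraries 0.17). A library with cells of both sexes is excluded, since Y-linked UMIs numbered 0 (0% of the 2010.0 expected). Of 5 female-biased genes measured, 4 were highest in library 7, so this kidney likely came from a female, and the labels state no sex.

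Cluster 11 held 2.209% of library 1 (95% Wilson interval 1.74% to 2.81%, counting error only), against a median of 0.37%. In library 3, Hbb-bs reached 1339 CPM (exact Poisson 95% interval 1304 to 1374, counting error only), against a median of 15.02. Hba-a1 reached 1325 CPM there (1291 to 1360.0), against a median of 7.66.

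Exchanging cluster labels within libraries gave at most 1007 genes in the other 31 of 32 splits between intercalated-like and principal-like cells, against 2128 with the real labels in the same fit, so 1 split of 32, the real one, was as large. For cluster 8 the other splits gave at most 1 gene, against 792 (principal-like) and 510.0 (intercalated-like), and 1 split of 8, again the real one, was as large, too few splits for a share under 0.05. In all of these comparisons the authors had set the clusters on the same counts. The real labels were thus bound to give the most genes, and the splits cannot test the grouping.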

How the results depend on the processing

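A count was taken as kept if it stayed within a fixed fold of its main value, so kept counts could still change. All 154 alternative values of the disease lists were kept in that sense. Acidosis genes highest in their class ranged from 3 to 5, and chronic kidney disease genes higher in theirs from 16 to 21. All 144 of the cluster shares moved by less than the SD between libraries. Most of these values left out 1 library, which cannot move a mean by as much as that SD. For them this outcome was fixed in advance. Even so, leaving out library 5 moved cluster 9 from 0.727% to 0.197%, and leaving out library 1 moved cluster 8 from 0.318% to 0.207% and cluster 11 from 0.724% to 0.477%. Results were kept by 71 of 90 gene counts, 162 of 190 for the collecting duct lists, 708 of 717 for named genes, 32 of 42 for positions and 46 of 50 for the proximal lists. Thinning cells to an equal depth left 423 higher and 391 lower genes between intercalated-like and principal-like cells, 126 and 126 for cluster 8 against principal-like and 99 and 98 against intercalated-like cells, with fewer genes tested. With at least 20 cells per sum, only libraries 1 and 6 kept cluster 8, with 178 lower genes against principal-like and 125 higher and 55 lower against intercalated-like cells. Of the main calls of cluster 8 against intercalated-like cells, 29.7% were shared at that setting. Only the compared clusters in the fit gave 240.0 higher genes against principal-like cells, with 2768 genes tested, and no library block gave 217 lower. With no low-count filter 482 were lower against intercalated-like cells, with 15051 genes tested. The main fit tested 6536 genes, so these counts are not like for like, and the cause was not tested. Leaving out 1 library gave 998 to 1093 higher and 899 to 1050.0 lower genes between both types, 239 to 382 lower for cluster 8 against principal-like cells, and 155 to 265 higher and 143 to 301 lower against intercalated-like cells.

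The position of cluster 8 over all called genes was 0.599 on the linear scale (added after seeing the data), 0.483 after thinning and 0.506 with no block. For genes higher in intercalated-like cells it was 0.547 on the linear scale, 0.680 with DESeq2 size factors, 0.570 with no filter and 0.677 with at least 20 cells, and for genes higher in principal-like cells 0.632, 0.537 with no filter and 0.432 with no block. With an estimated correlation 3 of 8 collecting duct lists stayed called and 1 of 3 proximal lists, with adjusted p of 0.204 for fatty acid oxidation and 0.118 for glycolysis, while fry, which tests a list against no change instead of against other genes and so asks another question, gave 0.00406 for proximal oxidative phosphorylation. Between both collecting duct types fry gave 0.000484 for Notch ligands, 0.000319 for the transcription factors, 0.000103 for Bartter, 1.04e-05 for chronic kidney disease and 0.0233 for dissociation genes, which camera did not call, and 0.074 for mitochondrially encoded genes, which it did. The glycolysis list reversed its direction between both types without library 3 (0.95) and library 4 (0.905), over a range of 0.627 to 0.969, and was never past the threshold. The cause of these was not tested. Removal of Scrublet calls and wild-type kidneys alone were not run.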

Other observations

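Cluster 10 held 1.28% ± 0.438 of cells (SD, n = 7) and was described by no single marker list. Its highest genes among the markers were Lyz2 at 13770 ± 4460 CPM, Plac8 at 5503 ± 1970 and S100a4 at 1051 ± 396 (SD, n = 7), with the monocyte receptor gene Csf1r at 242 ± 119 CPM. The collagen genes Col1a1, Col1a2 and Col3a1 had 0 UMIs in this cluster and Dcn had 1, although Plac8 and S100a4 stood in the fibroblast list. Of the dendritic cell markers 4 of 6 were highest here, among them Cd209a, and the macrophage gene C1qa stood at 4.98 CPM.

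The Kap gene, which is androgen-dependent in the proximal tubule, differed widely between libraries in cluster 3, from 40181 CPM in library 4 (exact Poisson 95% interval 39970.0 to 40400.0) to 1628 CPM in library 5 (1613 to 1644) and 166 CPM in library 7 (158 to 174). Jchain, a gene of plasma cells, reached 2489.6 CPM in library 3 (2442 to 2538) and 2641 CPM in library 4 (2604 to 2678) over all cells. The intervals hold counting error only. These are values of single libraries and were not tested.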
